A study of Mus musculus with 4 samples.

How the data were processed

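Reduced representation bisulphite sequencing, which reads CpG methylation in the CpG-rich fragments left by a restriction digest, was applied to genomic DNA of mouse neural stem cell cultures. Per the labels' protocols, the lines came from female embryos of embryonic day 14.5 with a conditional Smchd1 allele, an Xist deletion on the 129 X chromosome and an intact Xist on the Cast (castaneus) X chromosome. Part of each culture received Cre recombinase and puromycin resistance by retroviral transduction, with selection from 24 h, and cells were harvested 7 days after transduction.

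The deposited table holds percent methylation per CpG position, given by the authors for the 129 allele, the Cast allele and a column named Merged in each of 3 libraries, 9 value columns in all. Per the submitters' processing notes, bcl2fastq, Trim Galore 0.4.0 and Bismark 0.13.0 were used with the mouse build mm10. How reads were assigned to an allele, and which positions were kept, is not given in the sources used here. The table gives no read counts, so the depth behind every percentage is unknown and no interval that needs it was computed. Of the 4 libraries the labels describe, the del/del and del/fl libraries of line 98.8 and the library titled +/fl of line 98.6 have columns. The library titled +/del of line 98.6 was not analysed here. The genotype labels of the 2 libraries of line 98.6 contradict their titles, so the library is called "titled +/fl" throughout; by its title it carries a wild-type and a floxed Smchd1 allele, and by its genotype label a wild-type and a deleted allele, so its number of intact alleles is open. The del/fl columns carry the number 98.9 where the title says 98.8; they were matched by genotype, which occurs in no other library.

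The table has 38516 rows for 26173 positions. A position listed for both strands holds the same values in both rows and was used once. The listed strand goes with the level rather than with the sequence: positions listed as plus only had a mean level of 97.9% and those listed as minus only 0.588%, so strand was not used. The Merged columns were not used, because 10184 of the 14862 positions with every allele column above 20% are listed at 0 in each Merged column. The positions cover the genome unevenly, with 3369 on the X chromosome and 22804 on autosomes, of which chromosomes 1, 3 and 15 hold 5901, 6218 and 4800.

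Positions at most 100 bp apart were joined into clusters. The outermost position at each end was left out, a choice made after the data were seen because such positions are often fully methylated in clusters that are otherwise unmethylated. Clusters with at least 5 inner positions were kept, and the level of a cluster is the mean of its inner positions. This gave 1067 clusters, 105 on the X and 962 on autosomes. Clusters were called low on 129 where the mean of the 129 allele over the 3 libraries was at most 10%, high where it was at least 70% and intermediate otherwise. Genes were taken from RefSeq spans of the same build extended by 1000 bp, and 914 clusters (85.7%) had a gene. The annotation used here gives no exons or strand, so places are given only relative to the ends of the gene span.

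The tests fixed before the data were examined, an exact test per feature and a count model with line as a term, need counts and were not run. Each group has 1 library, so no p-value is given for a difference between libraries; the p-values of the closing section compare clusters within these libraries, and clusters are not independent replicates. Differences are in percentage points. A cluster was counted as higher or lower at a difference of at least 10 points. As background, the same difference was taken over autosomal clusters with a pair mean of 10 to 90%, with its 2.5 and 97.5 percentiles. The median of a set was placed among the medians of 10000 random lists of the same size, matched on level in steps of 10 points and on number of positions; for X clusters the lists came from autosomes. This describes these libraries and is not a test of the genotypes. The rule for named clusters, fixed before the data were examined, took the largest 12 in each direction where del/del differed with 1 sign from the other libraries, the largest 6 in each direction on the X, and members of gene lists; size replaced the call that counts would have given. The largest 12 were also taken for the comparison of the lines. Arhgap6, Fmr1, Map7d3, Pdk3, Phf6, Wdr45, Bhlhb9 and the clusters of the closing section were chosen after their values were seen. Some clusters that the rule names are not reported here. Gene lists, also fixed then, were X escape genes, imprinted genes, germline genes, neural stem cell, neuron, astrocyte, oligodendrocyte, microglia, and fibroblast and endothelial markers, pluripotency genes, housekeeping genes, DNA methylation machinery, clustered protocadherins, Hox clusters, the Rhox cluster, vomeronasal and olfactory receptors, and zinc finger proteins; a gene counted as measured with at least 3 inner positions.

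The steps were tested on simulated percentages of the 1067 clusters. Noise was normal, of the same form on the X and autosomes, with an SD of at most 4 points for a difference. The SD of the real Cast difference between del/fl and titled +/fl on autosomes was 8.19 points. The runs therefore check the calculation, and not whether autosomes are a fair background for the X. For the comparison of del/fl with +/fl, a shift of -15 points put into 40 X clusters came back as a mean median of -14.9 points, below the random range in 20 of 20 runs; without a shift, 1 of 20 runs lay below it. Alternatives for the minimum difference, the set of clusters, the summary of a cluster and the use of mean or median were computed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.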

Results

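Allele-specific CpG methylation was compared in 3 neural stem cell libraries that differ in Smchd1, which encodes a chromatin protein that acts on the inactive X chromosome. The libraries were Smchd1 del/del and del/fl of line 98.8 and the library titled +/fl of line 98.6, with 1 library per group and no replicates. Xist, the non-coding RNA that starts X inactivation, is deleted on the 129 X in these females, so the Cast X is the one that can be inactivated. Read depth is unknown, and differences between libraries are set against the same differences on autosomes. Neither Smchd1 (chromosome 17, 71344489 to 71475366, mm10) nor Xist (X, 103460373 to 103483233) had a position in the table, so the deletions could not be checked from it.

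The alleles differed more on the X chromosome than on autosomes, and the libraries differed mainly on the Cast X. Over 3369 X positions, the mean level of the Cast allele was 75.7% in the library titled +/fl, 68.0% in del/fl and 68.8% in del/del, while the 129 allele stood at 66.4%, 64.9% and 65.0%. Over 22804 autosomal positions the Cast means were 51.2%, 50.8% and 50.9%, and the 129 means 51.6%, 51.0% and 51.0%. Across these single positions the SD was 27.1 to 31.7 points for the Cast X and 40.6 to 40.8 points for the 129 X.

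At 54 X clusters with low methylation on 129, of which 38 lay within 1000 bp of an end of a gene, the mean Cast level was higher in every library. The mean 129 level was 1.14% in titled +/fl, 1.01% in del/fl and 0.978% in del/del. The mean Cast level was 53.1% (SD 21.7 across clusters), 35.4% (SD 20.01) and 35.7% (SD 21.4). Cast exceeded 129 by at least 20 points at 46, 39 and 40 of the 54 clusters. Choosing clusters low on 129 leaves almost no room for the reverse. At 625 autosomal clusters low on 129, Cast exceeded 129 by that much at 0, 1 and 1. In titled +/fl the Cast allele stood below 10% at 5 of the 54, among them Ddx3x, an RNA helicase gene that escapes X inactivation, and Jpx, a non-coding gene beside Xist. Further clusters were below 10% in del/fl or del/del only. An X cluster without a gene (12007293 to 12007396) had 20.8% in titled +/fl, 1.32% in del/fl and 0 in del/del. At 36 X clusters high on 129 the order was the opposite. The means on 129 and Cast were 89.2% and 78.5% in titled +/fl, 86.7% and 71.3% in del/fl, and 86.7% and 73.1% in del/del. At 194 autosomal clusters high on 129 they were 89.4% and 88.5% in titled +/fl.

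**Figure D1:**
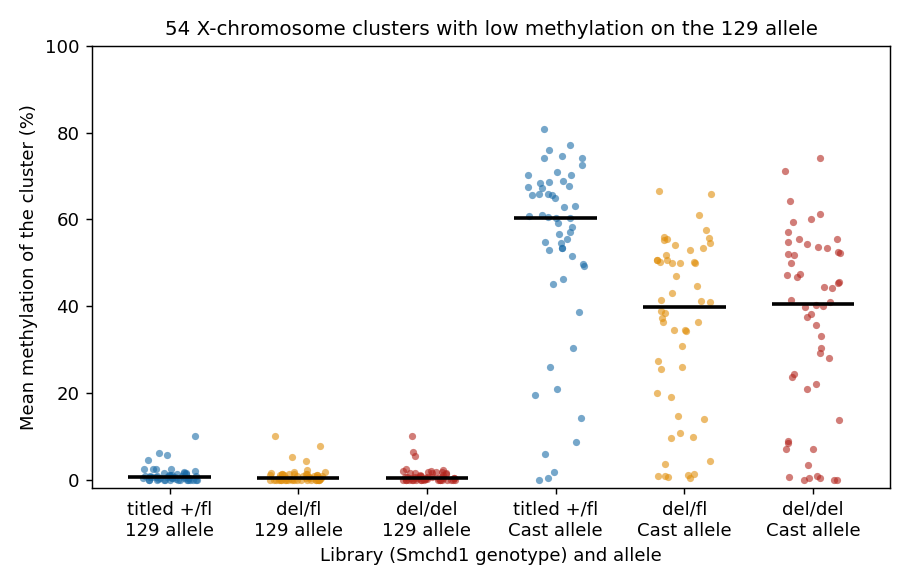
Mean methylation (%) of each of the 54 X clusters low on 129, by library and allele; each point is a cluster and each black bar the median. The Cast medians are 60.2% in titled +/fl, 39.9% in del/fl and 40.5% in del/del, and the 129 medians are 0.553%, 0.434% and 0.418%.

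The comparison of del/del with del/fl in line 98.8 asks what the loss of the remaining Smchd1 allele does to methylation; the columns of the del/fl library carry another line number than its title, so that the pair is from 1 line rests on that title. At the 54 clusters low on 129 the median Cast difference, del/del minus del/fl, was -0.402 points (SD 5.07 across clusters). Of these clusters 2 were higher by at least 10 points in del/del and 0 were lower. The higher clusters were Hccs, which encodes the enzyme that attaches haem to cytochrome c (54.2% in del/fl and 71.2% in del/del), and Bhlhb9 (50% and 60.2%). In titled +/fl they stood at 74.5% and 68.4%, so del/del was not above that library at either. Among clusters near a gene end, Cast levels were close at Fmr1, a regulator of translation (40.9% and 40.0%), and at Pdk3, a pyruvate dehydrogenase kinase gene (53.0% and 53.3%). They were further apart at Map7d3 (51.8% in del/fl and 61.3% in del/del) and Arhgap6 (61.1% and 52.3%).

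Among all 1067 clusters, the Cast allele was higher in del/del at 17 and lower at 15, and the 129 allele was higher at 11 and lower at 14. Of these, del/del also lay on the same side of titled +/fl at 11 and 13 on Cast and at 6 and 9 on 129. The largest Cast difference was at an X cluster without a gene (80830317 to 80830423), at 55.0% in del/fl and 75.8% in del/del, against 73.6% in titled +/fl. An autosomal cluster without a gene on chromosome 1 (121178144 to 121178357, 11 positions) had Cast levels of 43.9% and 63.9%. Of clusters inside genes, Cast methylation was higher in del/del at Ctnnd2, which encodes a neuronal catenin (1.33% and 19.2%), Gpr25 (31.8% and 48.2%), Rbm46 (16.7% and 28.3%), Cacna1e, a calcium channel gene (40.4% and 51.7%), and Cyp1b1 (32.6% and 43.0%). On 129 it was higher at Zfp978 (26.1% and 40.4%), Espnl (50.4% and 62.2%), Umod (84.1% and 94.7%) and Rwdd3 (80% and 90%). Cast methylation was lower in del/del at Agap2 (59.1% and 43.7%), Cdh18, a cadherin gene (88.7% and 73.5%), Gstm5 (14.3% and 3.13%), Bcan, which encodes a proteoglycan of the brain matrix (92.8% and 82.0%), and Pbxip1 (76.7% and 66.0%). The 129 allele was lower at Cacna1i (86.6% and 71.9%) and at Mei1, a meiosis gene (16.7% and 4.76%). Levels in titled +/fl were close to del/del at Cyp1b1 (Cast 42.7%), Pbxip1 (Cast 66.5%), Umod (129, 93.3%), Rwdd3 (129, 88.3%) and Cacna1i (129, 72.5%). They were closer to del/fl at Ctnnd2 (Cast 3.85%), Gpr25 (Cast 36.5%), Agap2 (Cast 55.5%) and Cdh18 (Cast 88.0%). Further X clusters with a Cast difference of at least 10 points were Eda, a signalling ligand gene (53.8% in del/fl and 71.5% in del/del), Elf4 (43.9% and 54.8%) and 1700080O16Rik (57.9% and 46.8%). In titled +/fl the Cast levels of Eda, Elf4 and 1700080O16Rik were 77.9%, 62.1% and 66.1%.

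Over all 105 X clusters the median Cast difference between del/del and del/fl was -0.0368 points, at percentile 61.6 of the random autosomal lists. The 54 clusters low on 129 stood at percentile 16.1, inside the random range of -0.958 to 0.890. The 36 clusters high on 129 had a median of 1.54 points, at percentile 99.2 and above the random range of -2.47 to 1.17, with 4 clusters higher and 3 lower by at least 10 points. On the 129 allele of the X the median was 0 points at clusters low on 129, where that choice left little room for a difference. The autosomal background was -10.8 to 11.5 points for Cast and -12.1 to 10.7 points for 129, so some of the named clusters lie inside it. The counts move with the number of positions asked of a cluster. The 57 values over both alleles became 164 with at least 3 inner positions and 9 with at least 10. With the median of all positions as the level, 20.7% of X clusters low on 129 were lower in del/del by at least 10 points, against 0 with the mean of inner positions.

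Line 98.8 was compared with line 98.6 to give a scale for the difference within line 98.8. The Cast X was less methylated in del/fl than in the library titled +/fl, while the median was 0 on autosomes and differences on the 129 X were smaller. Of the 962 autosomal clusters 625 were low on 129, with little room to fall. At the 194 high on 129 the median Cast difference from titled +/fl was -0.957 points for del/fl (10 lower, 2 higher) and -1.05 points for del/del (12 lower, 2 higher). At the 143 intermediate clusters it was 0.0588 and 0 points. At the 54 X clusters low on 129 the median Cast difference, del/fl minus titled +/fl, was -17.4 points (SD 10.7 across clusters), with 41 clusters lower by at least 10 points and 0 higher. For del/del minus titled +/fl the median was -18.4 points (SD 11.7), with 39 lower and 0 higher. The autosomal background for Cast was -13.8 to 14.1 points for del/fl and -12.9 to 13.4 points for del/del. Below it lay 36 and 34 of the 54 clusters. Both medians lay below those of all 10000 random autosomal lists, whose ranges were -1.76 to 0.613 and -1.90 to 1.17 points. Over all 105 X clusters the medians were -11.9 and -11.5 points, and at single X positions they were -3.87 and -3.33 points.

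Clusters with much lower Cast levels than in titled +/fl were spread over the X. Clcn5, which encodes an endosomal chloride transporter (X, 7319257 to 7319363), had a Cast level of 68.9% in titled +/fl, 27.3% in del/fl and 23.5% in del/del. Rnf128, a ubiquitin ligase gene (139610570 to 139610680), had 52.9%, 14.7% and 8.44%. Tsc22d3, a glucocorticoid-induced gene (140599318 to 140599412), had 58.2%, 20% and 20.9%, and an internal cluster of Nhsl2 (101954244 to 101954407) had 45.1%, 9.81% and 7.06%. Fgf13, Alg13, Spin4, Gm715 and Gpr50 had Cast levels of 64.8%, 53.5%, 46.2%, 80.8% and 65.6% in titled +/fl and of 34.3%, 25.6%, 19.05%, 54.5% and 41.1% in del/fl. At other clusters the difference was smaller. Wdr45, an autophagy gene, had Cast levels of 55.5% in titled +/fl, 55.5% in del/fl and 54.3% in del/del, and Pdk3 had 53.5%, 53.0% and 53.3%. At the Phf6 cluster from 52913467 to 52913596 they were 75.9%, 66.5% and 74.1%, and at Map7d3 they were 60.2%, 51.8% and 61.3%.

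**Figure D2:**
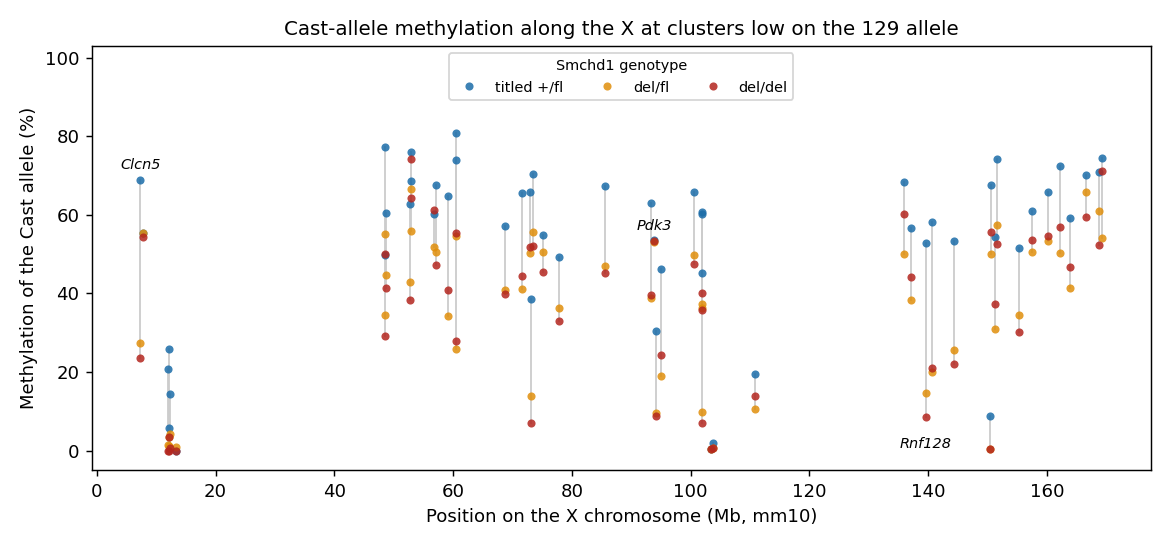
Cast-allele methylation (%) at the 54 X clusters low on 129 against position on the X (Mb); each point is a cluster in a library, and grey lines run from titled +/fl to the lower of del/fl and del/del. Cast levels at Clcn5 are 68.9% in titled +/fl and 27.3% in del/fl, while at Pdk3 they are 53.5% and 53.0%.

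Del/fl and del/del shared the titled +/fl library as control. Of the 54 clusters, 37 were lower by at least 10 points in both; independent lists of the same sizes would share 29.6, and simulated libraries without an effect shared 0.13 on average. The covariance of the 2 sets of differences across clusters was 113, against 12.2 in the simulation, an excess of 101. The simulated noise was set from the median absolute deviation of the autosomal differences, which gives little weight to their tails. The SD of these differences was larger, at 8.19 points for del/fl and 8.23 points for del/del. These differences include the Magohb cluster on chromosome 6, at 83.6 and 85.2 points, and the SD without it was not computed. The simulated overlap and covariance are therefore low for such tails, and the size of the excess is not settled. With a single control library, part of the overlap may come from that library.

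At X clusters high on 129 the median Cast difference was -6.98 points for del/fl and -3.37 points for del/del against titled +/fl, at percentile 0 and percentile 6.47 of the random lists. On the 129 allele of the X, the medians at clusters low on 129 were -0.0151 and -0.0465 points. The choice of these clusters by their 129 mean left almost no room for a fall and limited a rise. At clusters high on 129 the medians of the 129 allele were -1.88 points for del/fl (percentile 12.3, with 27 of 36 clusters below 0) and -2.26 points for del/del (percentile 6.37). Over all 105 X clusters the 129 median was -0.376 points for del/fl, at percentile 0.89 and below the random range of -0.325 to 0.0828, with 7 clusters lower and 1 higher by at least 10 points; for del/del it was -0.254 points at percentile 14.9. Over the 962 autosomal clusters the Cast allele of del/fl was higher than titled +/fl at 17 and lower at 17, with a median of 0. The largest difference was at Magohb, a gene of the exon junction complex (chromosome 6, 131293077 to 131293212, 20 positions, inside the gene within 1000 bp of its end): the Cast allele had 0.441% in titled +/fl, 84.0% in del/fl and 85.6% in del/del, and the 129 allele had 0.179%, 0.106% and 0.317%. On 129, Dlg2, a synaptic scaffold gene, had 62.5% in titled +/fl and 92.4% in del/fl, and C7, a complement gene, had 85% and 63.0%. Gbx2, a homeobox gene of hindbrain patterning, had Cast levels of 27.6% and 41.8% and 129 levels of 14.6% and 29.0%. Line and Smchd1 genotype change together in this comparison and cannot be told apart with these libraries, and by its genotype label the library titled +/fl would be +/del, with 1 intact Smchd1 allele as in del/fl.

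**Figure D3:**
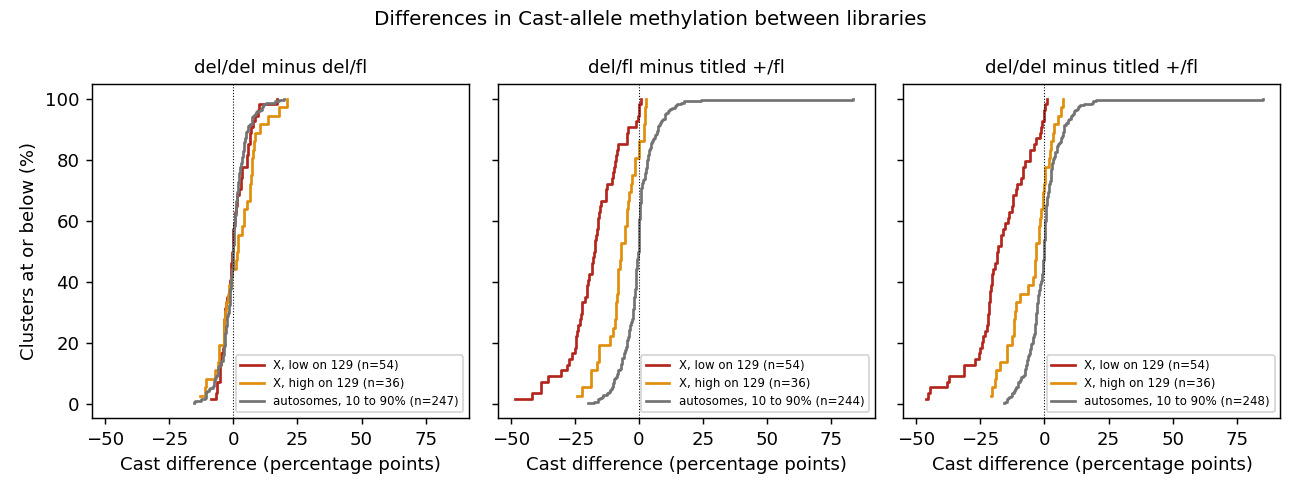
Cumulative share of clusters (%) against the Cast difference (percentage points) for the 3 pairs of libraries; red is X clusters low on 129, orange X clusters high on 129 and grey autosomal clusters at 10 to 90%. The red medians are -0.402 points for del/del minus del/fl, -17.4 for del/fl minus titled +/fl and -18.4 for del/del minus titled +/fl.

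Of the gene lists, the measured X escape genes were nearly unmethylated on the Cast X in each library. With 4 of 12 members measured, Ddx3x had Cast levels of 0 in titled +/fl, 0.909% in del/fl and 0 in del/del, and Kdm6a, a histone demethylase gene, was listed at 0 in each. Jpx had 0.391%, 0.331% and 0.402%. Firre, a non-coding gene (cluster at 50623101 to 50623226, inside the gene), had 0.571%, 0.588% and 0 on Cast but 86.7%, 93.6% and 90.2% on 129. Of the 4, 0 were higher and 0 lower by at least 10 points in del/del than in del/fl, with a median Cast difference of -0.294 points at percentile 22.4 of matched lists. Their Cast levels left no room for a fall of 10 points, so on Cast only a rise could have been counted.

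Of 43 imprinted genes 2 were measured, both on chromosome 15. Peg13, an imprinted non-coding gene inside Trappc9, had 89.5% on 129 and 36.8% on Cast in titled +/fl, 76.0% and 29.7% in del/fl, and 89.2% and 31.1% in del/del; Trappc9 had Cast levels of 59.5%, 59.1% and 58.2%. Of 33 Rhox genes, a reproductive homeobox cluster on the X, 3 were measured, with a median Cast difference of 2.52 points between del/del and del/fl (percentile 76.2). Rhox1, Rhox7a and Rhox9 had Cast levels of 53.4%, 80.3% and 79.3% in del/fl and 61.3%, 81.3% and 81.8% in del/del. On 129, Rhox9 was the 1 member past 10 points in that pair, with 76.0% in del/fl and 91.5% in del/del, against 92.6% in titled +/fl. Of 369 zinc finger genes 17 were measured, with a median of 0.0593 points (percentile 73.7) and 0 members past 10 points in that pair; against titled +/fl, the Cast allele of del/fl was lower at Zfp185 on the X (65.9% and 50.2%) and at Zfp180 (77.3% and 66.3%). Sox2, a transcription factor gene of neural stem cells, was nearly unmethylated, with Cast levels of 0.813%, 0.482% and 0.123% in titled +/fl, del/fl and del/del, and Slc1a3, a glial glutamate transporter gene, was methylated at its measured positions (90.2%, 91.0% and 87.8%). Sox10, the only oligodendrocyte marker measured, had 8.24%, 6.03% and 4.08%, and Hormad1, the only germline gene measured, had 85.9%, 81.8% and 73.3%. The housekeeping gene Hprt on the X had 55.4%, 40.8% and 44.8%. Of the receptor genes, Vmn2r1 had Cast levels of 60.5%, 50.1% and 40.9% and Vmn2r29 had 56.9%, 69.9% and 70.3%. No member was measured for the lists of neuron, astrocyte, microglia, or fibroblast and endothelial markers, pluripotency genes, DNA methylation machinery, clustered protocadherins and Hox clusters.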

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

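The tests in this part were chosen after the results were seen. A cluster inside Asb18 (chromosome 1, 89993129 to 89993275, 5 positions) had allele differences in opposite directions: Cast minus 129 was 23.3 points in titled +/fl, -26.3 points in del/fl and -11.9 points in del/del. It was the single cluster of 1067 with at least 20 points in each direction, the difference was not tested, and its depth is unknown.

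The Cast X was less methylated in del/fl and del/del than in titled +/fl at X clusters low on 129, by 33.4% and 32.8% of the mean level. If part of the cells had inactivated the 129 X instead, the 129 allele would gain about 17.8 and 17.4 points at the same clusters. Its mean change was -0.124 points (SD 1.14) in del/fl and -0.158 points (SD 0.964) in del/del. These clusters were chosen for a 129 mean of at most 10% over all 3 libraries. A gain of that size in both libraries could have taken a cluster out of the set. Such a cluster would still be among all 105 X clusters, which were taken at any 129 level. Against titled +/fl, 129 was higher there by at least 10 points at 1 cluster in del/fl and 0 in del/del. It was lower by as much at 7 and 2. These counts argue against inactivation of the 129 X in part of the cells, for the clusters measured. Cells with an active Cast X, or 129 reads counted as Cast, would raise Cast at X clusters high on 129 and lower on Cast in titled +/fl. At the 14 such clusters the rise would be 7.90 and 7.75 points, if an active Cast X had the level of 129. The mean Cast change there was -6.13 points (SD 5.80) and -5.27 points (SD 7.80). A mean rise was not seen, but a fall from another source could hide it, so a part played by such cells or reads is not excluded. Lower methylation or a conversion error on every chromosome would lower autosomes by a like share, but their mean Cast level at clusters of 10 to 90% changed by -0.278% and -0.174%. Whether the difference belongs to the line or embryo or to the Smchd1 genotype stays open. Of line 98.6, 0 libraries with a del allele by their title have columns, so line and genotype cannot be told apart. By its genotype label the library titled +/fl would be +/del, with 1 intact Smchd1 allele as in del/fl. Not even a difference in dose from del/fl is therefore certain.

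Unmethylated clusters often ended in a fully methylated position. Of 380 clusters with at least 9 positions and an unmethylated core, 363 (95.5%) had an outermost position at 80% or more, at similar levels in the 3 libraries and on both alleles (97.6% to 97.8%). To test methylation that spreads in from the flank, methylated ends were chosen only on the positions past the middle of the cluster (median at most 10%), so that partly methylated positions near the end stayed in. It would leave the neighbours of these ends partly methylated, but at 606 such ends in 453 clusters the median of the next position was 0.529%, with an upper quartile of 1.38%, and 6 were at 20% or more. Other explanations, such as end repair of the library fragments, were not tested and stay open.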

How the results depend on the processing

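Of 124 alternative values, 83 moved by less than the yardstick (1.5 times for counts and shares; for levels and differences, the SD of the same difference over autosomal clusters, since there are no replicates). The settings on clusters (joining distance, number and summary of positions, cutoff on 129), single positions and the mean over clusters were added after the data were seen. The lower Cast X of line 98.8 at clusters low on 129 kept its direction under all 10 alternatives, from -18.9 to -16.5 points for del/fl and from -19.7 to -16.7 points for del/del against titled +/fl; del/del minus del/fl ran from -0.666 to 0.557 points. Over all X clusters, del/fl minus titled +/fl was -16.2 points with at least 10 inner positions and -3.87 points at single positions, and del/del minus titled +/fl was -3.33 points there. The share of X clusters low on 129 that were lower by the minimum became 38.9% for del/fl and 44.4% for del/del at 20 points, and, for del/del against del/fl, 5.56% with at least 3 inner positions and 20.7% with the median of all positions. Counts of values past the minimum in del/del against del/fl, 57 over both alleles, became 1 at 20 points, 1922 with no minimum, 164 with at least 3 and 9 with at least 10 inner positions, 27 with the mean and 109 with the median of all positions; on autosomes alone there were 44, and 39 had 1 sign against both other libraries. For del/fl against titled +/fl, 136 became 29 at 20 points, 1913 with no minimum, 337 with at least 3 and 41 with at least 10 inner positions. The cause was not tested, apart from the minimum itself.

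Levels depended on the summary; the cause was not tested. For titled +/fl, del/fl and del/del in this order, medians over X positions were 90.5%, 87.9% and 88.2% on 129 and 86.2%, 78.1% and 80% on Cast, and means over X clusters 37.0%, 35.7% and 35.6% on 129 and 63.1%, 50.1% and 50.9% on Cast. On autosomes the medians were 72.8%, 68.9% and 69.6% on 129 and 70.7%, 68.0% and 68.6% on Cast, and the means over clusters 23.5%, 23.3% and 23.2% on 129 and 23.4%, 23.3% and 23.3% on Cast. Coverage minima, thinning to equal coverage, the exact tests, and the count and linear models with line as a term were not run, as the values carry no counts and 3 libraries leave no residual degrees of freedom with that term. The fit without the line term was not run, because its residual would be the difference between the lines, and the comparison of titled +/del with titled +/fl was not run. No paired analysis was possible because each group has 1 library. Unknown depth limits every single cluster named here.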

Other observations

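The tests in this part were chosen after the data were seen. A few autosomal clusters differed widely between the alleles, with the same allele higher in all 3 libraries. Gm30421 (chromosome 17, 87041734 to 87041855, 15 positions) had 83.8%, 88.7% and 89.8% on 129 and 8.38%, 14.48% and 10.99% on Cast in titled +/fl, del/fl and del/del. Ddx20, a helicase gene (chromosome 3, 105687227 to 105687304), had 32.1%, 58.1% and 46.1% on 129 and 1.04%, 0 and 0 on Cast. Vmn2r29 (chromosome 7, 7278135 to 7278209) had the opposite order, with 14.0%, 14.7% and 8.33% on 129, as did a cluster without a gene on chromosome 3 (57136745 to 57136896), with 46.9%, 35.5% and 35.8% on 129 and 78.2%, 74.7% and 67.2% on Cast. Across the 962 autosomal clusters Pearson's r of the Cast levels was 0.996 between del/del and del/fl and 0.992 between each of them and titled +/fl; clusters are not independent replicates.

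The Cast level of line 98.8 as a share of that in titled +/fl differed between X clusters. At the 49 clusters low on 129 with a Cast level of at least 10% in titled +/fl, the mean of del/fl and del/del was between 3.16% and 99.4% of the titled +/fl level, with a median of 68.5%. A lower level on the whole chromosome would give similar shares. The hypothesis that the place in the gene goes with the share was tested after the cluster levels were seen, across clusters, which are not independent. At 35 clusters within 1000 bp of an end of a gene the median share was 70.9%, and at 14 elsewhere it was 32.7%, a difference of 38.3 points (permutation test, two-sided, p = 2.0e-05, adjusted p = 4.0e-05 over 2 relations). The clusters elsewhere lay inside genes or had no gene. The lowest shares came from clusters close together on the X, an internal Bcor cluster (13.5%) and clusters without a gene from 12007293 (3.16%) and 12252459 (16.9%). Their Cast levels in titled +/fl were 26.0%, 20.8% and 14.3%, and the permutation treated them as separate units. The internal Nhsl2 cluster (18.7%) and Rnf128 (21.8%) also had low shares, but Tceanc (89.1%) and Smim9 (87.6%) did not. Clusters elsewhere also had a lower median Cast level in titled +/fl, 49.0% against 63.1%. The upper quartiles of the share were close, at 77.7% near a gene end and 76.0% elsewhere, while the lower quartiles were 64.1% and 19.5%. The difference in share therefore rests on part of the clusters elsewhere. The share divides by the level in titled +/fl, and differences in points were not compared between the places. Place and level may both play a part, and no library gives an earlier level of line 98.8 itself. Genes were placed by their longest span, so an inner promoter counts as elsewhere.

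Distance from Xist was tested in the same way. Across the 49 clusters, which are not independent, the share had a Spearman rho of 0.153 with distance (permutation p = 0.293, adjusted p = 0.293) and a Pearson r of -0.0811 (permutation p = 0.578), and r was -0.114 without the 2 clusters farthest from the median distance. No relation was detected, and a weak relation is not excluded.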
